A study of Mus musculus with 21 samples.

How the data were processed

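Polyadenylated RNA was measured in 21 mouse mammary tumours. Per the labels' protocols, tumours were frozen and ground, RNA was extracted, stranded mRNA libraries were prepared, and single-end reads of 50 nucleotides were sequenced on a HiSeq 2500. Per the submitters' processing notes, the tools were STAR 2.5.2a, SAMtools 1.3.1, Picard 2.9.2 and edgeR, with the mouse build mm10; the role of each tool, the gene annotation, the strand setting and the treatment of reads matching several genes are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene, with no normalization, and the columns gave Entrez identifiers, symbols and the 21 tumours. In 10202 of the table's 24028 rows an extra leading cell held the row number, so each row was read from its last 25 cells. Gene positions are from a RefSeq gene table of GRCm38.p6, the assembly on which mm10 is built, matched by Entrez identifier for 23968 genes; 14 genes had no symbol, and 1175 had 0 counts in every tumour.

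Tumours were assigned to groups from their titles, and every count column was matched to its tumour by the title. Total counts ranged from 13337848 to 24873844 per tumour. The chi-square per degree of freedom between tumours of 1 group was at least 17.6 (stable 2 against stable 3), above sampling noise, so that no tumour was counted as a repeat of another. Each tumour was 1 replicate. The titles also hold a code, whose meaning the labels do not give and which tumours share within a group, and a digit and letter after it; both were used in alternatives or tests.

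The tests, samples, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Counts were filtered with filterByExpr by group, which kept 15792 genes, scaled with TMM factors, and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on all 21 tumours, with a contrast for each pair of groups and no covariates. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene is called, or said to rise or fall, at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F, and 95% intervals use the t distribution with the total degrees of freedom. CPM values are those of edgeR's cpm function with TMM-scaled totals and are given as mean ± SD. Median log2 fold changes over all genes were -0.02, -0.005 and -0.01 for relapse against vehicle, stable against vehicle and relapse against stable.

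For gene lists, camera (limma 3.58.1) was run on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 29 lists with at least 3 measured genes; 30 lists had been fixed. It was run again with an estimated correlation, under which 0, 1 and 0 lists were called in the 3 comparisons. Members are counted over all genes and adjusted over the list alone. A list's score in a tumour is the mean log2 CPM of its members minus the mean over all tumours. Erbb3, Fos, Egr1, Atf3, Ddit4, Spred1 and Spred2 each stand in more than 1 list. Skeletal muscle scores were compared by two-sided exact permutation tests that exchanged single tumours and did not keep title codes whole.

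Genes are named by this rule: 10 fixed genes (among them Nf1, Pik3ca, Irs2, Insr, Erbb3, Pik3ip1, Ccnd1, Dusp6 and Mki67); the 8 highest and 8 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1, leaving out predicted genes and immunoglobulin segments; where fewer than 4 are called in a direction, the lowest unadjusted p to make 4; and up to 4 members of lowest p from each list past its camera test or with at least 25% of its members called. Foxo1 and Fasn, which are members of lists, and genes said so in the text, were chosen after their values were seen. Some genes that meet the rule are not reported here.

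Alternatives were DESeq2 (1.42.0) size factors and upper quartile factors in edgeR, the DESeq2 Wald test, limma voom with sample quality weights or with the title code as a random effect, no filter, a fit of only the 2 groups, a block for the replicate number, counts summed per title code within a group, 1 tumour per code, an additional limit of 1 on the absolute log2 fold change, and leaving out each tumour in turn. Keeping 1 tumour per code took the lowest replicate number of each code. Of the vehicle tumours it kept 1, 3 and 5, and so left out 2, 6 and 7. Fits without vehicle 2, 6 and 7, alone or with summed counts, and list tests without stable 1, were added after seeing the data. Each comparison was also repeated on 100 divisions of its 14 tumours into 7 and 7, the real one included, and those with vehicle on the 78 and 8 divisions that keep title codes whole. The overlap of the comparisons with vehicle was set against 10 simulations of unchanged groups.

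The scripts were tested on simulated counts with 200 genes changed. Between relapse and vehicle, 52% of genes changed 2-fold and 84.5% of those changed 4-fold were recovered; the shares were 46.5% and 83.5% for stable against vehicle, and 46% and 87% for relapse against stable. In a simulation with 1 of 29 lists shifted 1.5-fold, camera called 2 lists. Expression along chromosomes was scanned in each tumour as the running median, over 9 neighbouring genes, of log2 CPM minus the gene's median over tumours, for 12223 genes with a mean log2 CPM of at least 2. Figures were drawn with matplotlib 3.10.9.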

Results

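RNA was sequenced from 21 mammary tumours of WAP-Cre/PIK3CA-H1047R mice, in which a recombinase under a milk protein promoter switches on a mutant catalytic subunit of PI3K-alpha in mammary epithelium. The animals had received vehicle (DMSO) or BYL719 (alpelisib, an inhibitor of PI3K-alpha), and the treated tumours were labelled relapse or stable. The design text of the series names the treated groups responding and stable and does not say how responding relates to relapse; the sample labels are followed here, and they do not say when tumours were collected. Each of the 3 groups held 7 tumours, named below by group and replicate number. Total counts per tumour ranged from 13337848 (stable 3) to 24873844 (vehicle 2), with 21043399 to 24873844 in vehicle, 17722622 to 21431465 in relapse and 13337848 to 24648463 in stable tumours. The sample titles also carry a code, which took 3 values among the vehicle, 7 among the relapse and 4 among the stable tumours, with 2 codes present in both the relapse and the stable group. The labels do not say whether a code is an animal, so the p-values below measure the spread between tumours, some of which possibly share an animal.

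Vehicle 2, 6 and 7 stood apart from every other tumour. On the first principal component, which held 45.9% of the variance of the 1000 most variable genes, they lay at 97.8, 99 and 76.7, and the next tumour, stable 1, lay at 32.5. Their scores for basal and myoepithelial markers (mean log2 CPM of the list minus its mean over all tumours) were 2.41, 2.75 and 2.25, and the next highest was 0.779 in vehicle 3. Their neutrophil marker scores were -3.21, -2.48 and -1.52, but here vehicle 7 did not stand apart, with stable 1 at -1.59. Skeletal muscle marker scores lay between 2.38 and 4.36 in 6 relapse tumours, at -3.2 in relapse 4, at 2.9 in stable 5, and at 0.679 or lower in the remaining stable tumours and all vehicle tumours.

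**Figure D1:**
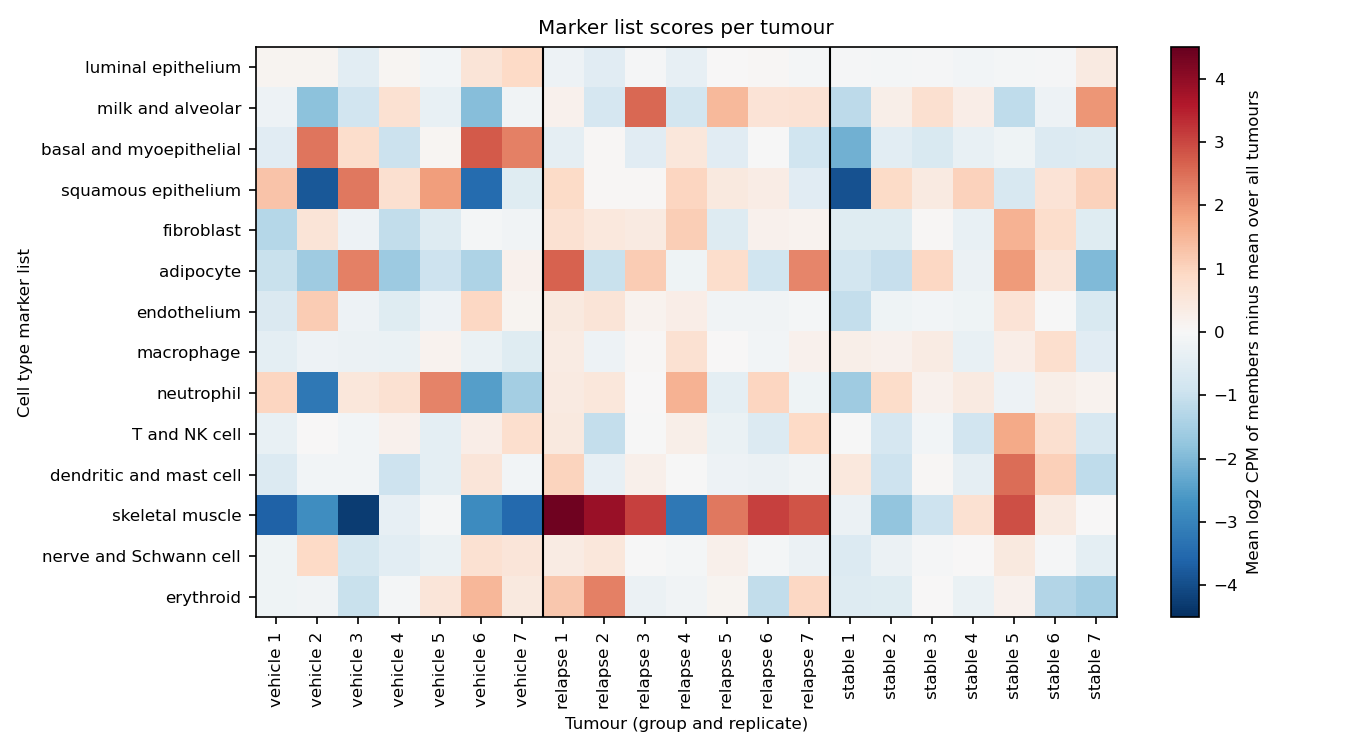
Scores of 14 cell type marker lists in the 21 tumours, coloured by mean log2 CPM of the list's members minus the mean over all tumours, with black lines between the groups. Vehicle 2, 6 and 7 have basal and myoepithelial scores of 2.41, 2.75 and 2.25, and relapse 1, at 4.36, has the highest skeletal muscle score.

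The series concerns resistance to PI3K-alpha inhibition and the loss of Nf1, and relapse against vehicle asks which transcripts differed in tumours that relapsed under BYL719. Irs2, an adaptor of the insulin and IGF1 receptors (Entrez gene 384783, chromosome 8, 10984681 to 11008929, GRCm38), rose from 21.1 ± 6.33 CPM in vehicle to 50.9 ± 13.1 CPM in relapse tumours (mean ± SD, n = 7 each). Its log2 fold change was 1.27 ± 0.20 (SE, edgeR adjusted p = 0.00115), and 7 of 7 relapse tumours lay above the vehicle median. The Irs2 call did not hold through all of these fits: counts summed per title code, leaving out vehicle 2, 6 and 7, and both together. Sc5d, a sterol desaturase of cholesterol synthesis, fell from 70.0 ± 18.8 to 38.3 ± 4.37 CPM (-0.87 ± 0.14, adjusted p = 0.00176). The skeletal muscle gene Myh4, a fast myosin heavy chain, rose from 23.5 ± 37.9 to 957 ± 784 CPM (5.35 ± 1.40, adjusted p = 0.0189; 0.0681 with counts summed per title code and 0.108 without vehicle 2, 6 and 7). The myoepithelial gene Cnn1, of a smooth muscle protein, fell from 297 ± 393 to 4.74 ± 2.63 CPM (-5.96 ± 1.26, adjusted p = 0.00687), with 4 of 7 relapse tumours below the vehicle median; it was at 0.37 (adjusted p = 0.745) without vehicle 2, 6 and 7. Of the other genes with a standard error in this comparison, Ckm, Myh2, Myh11 and Acta2 lay beyond the vehicle median in 6 of 7 relapse tumours, and the rest in 7 of 7.

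Among the 22 measured members of the list of PI3K feedback genes and FOXO targets, which growth factor signalling through PI3K and AKT normally represses, 9 rose and 1, Foxo1, fell (10 and 2 adjusted over the list alone). Besides Irs2, the receptors Igf1r (1.33 ± 0.21, adjusted p = 0.00167), Erbb3 (0.95 ± 0.20, adjusted p = 0.00685) and Insr (0.39 ± 0.11, adjusted p = 0.0294) rose, as did the cell cycle inhibitor Cdkn1b (0.58 ± 0.13, adjusted p = 0.0076). The list had a median log2 fold change of 0.41 and passed the camera test (adjusted p = 0.000457). That call was lost at an adjusted p = 0.174 with an estimated correlation. Without vehicle 2, 6 and 7 the list's median was 0.57 (adjusted p = 1.16e-06; adjusted p = 0.0637 with an estimated correlation), while Erbb3 (0.77, adjusted p = 0.066) and Cdkn1b (0.53, adjusted p = 0.0524) lost their calls. Insr lost its call with counts summed per title code (adjusted p = 0.0797) and without vehicle 1 (0.058) or relapse 1 (0.0543), 3 (0.0573), 6 (0.0591) or 7 (0.0732).

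The cholesterol and fatty acid synthesis list fell, with a median of -0.81 over 26 genes and a camera adjusted p = 1.16e-08, which became adjusted p = 0.476 with an estimated correlation. Of its members, 14 fell and 0 rose in edgeR's test (21 and 0 adjusted over the list alone; 3 members had a positive log2 fold change). Besides Sc5d, they included squalene synthase Fdft1 (-0.70 ± 0.13, adjusted p = 0.00406) and mevalonate kinase Mvk (-0.76 ± 0.15, adjusted p = 0.00473). The fatty acid synthase Fasn (0.64, adjusted p = 0.382) did not pass the test. The synthesis score was highest in vehicle 3, at 1.81. With vehicle 2, 6 and 7 left out the list's median was -0.95 (adjusted p = 1.09e-16; adjusted p = 0.146 with an estimated correlation).

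Oxidative stress and glutathione genes were lower by a median of -0.35 over 23 genes (camera adjusted p = 0.00137; adjusted p = 0.703 with an estimated correlation). Of these, 3 fell (5 adjusted over the list alone), including the quinone reductase Nqo1 (-2.03 ± 0.36, adjusted p = 0.00256) and Gclc, a subunit of the enzyme that starts glutathione synthesis (-0.75 ± 0.19, adjusted p = 0.0167). Without vehicle 2, 6 and 7, Gclc was at -0.28 (adjusted p = 0.258). In the list of ATF4 and unfolded protein response genes, with a median of -0.21 over 21 genes, 6 fell (9 lower and 3 higher adjusted over the list alone). They included Herpud1 (-0.86 ± 0.19, adjusted p = 0.00733), a gene of protein quality control at the endoplasmic reticulum, and Atf4 itself (-0.69 ± 0.19, adjusted p = 0.0242). The camera adjusted p of that list was 0.042, and it was an adjusted p = 0.947 with an estimated correlation. With vehicle 2, 6 and 7 left out, Herpud1 was at -0.57 (adjusted p = 0.0712) and Atf4 at -0.45 (adjusted p = 0.249). Atf4 also lost its call without vehicle 2 (adjusted p = 0.0784), vehicle 6 (0.0599), vehicle 7 (0.0689) or relapse 6 (0.0503), and the list lost its call with counts summed per title code (0.0696) and without stable 1 (0.0613).

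Of the 13 skeletal muscle markers, 11 rose (13 adjusted over the list alone), with a median log2 fold change of 5.05 (camera adjusted p = 5.64e-11; adjusted p = 0.442 with an estimated correlation). Muscle creatine kinase Ckm rose by 5.32 ± 1.29 (adjusted p = 0.0127) and the myosin heavy chain Myh2 by 4.98 ± 1.08 (adjusted p = 0.00732). The tumour scores for this list differed by 4.84 between the group means (two-sided exact permutation p = 0.0035, smallest of 3 comparisons, Benjamini-Hochberg adjusted 0.0105). The permutations exchanged single tumours, some of which share a title code. Of the 13 markers, 5 were called with counts summed per title code and 1 without vehicle 2, 6 and 7, where the median was 4.45 (adjusted p = 2.81e-09; adjusted p = 0.576 with an estimated correlation). In the latter fit Myh4 (4.58, adjusted p = 0.108), Ckm (4.56, adjusted p = 0.0801) and Myh2 (4.63, adjusted p = 0.0725) lost their calls; with summed counts Myh4 (adjusted p = 0.0681) and Ckm (adjusted p = 0.0563) did. Myosin heavy chain genes are similar in sequence, and how reads matching several genes were counted is not given in the sources used here.

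Of the 14 measured basal and myoepithelial markers, 6 fell (7 adjusted over the list alone), with a median of -2.34 (camera adjusted p = 0.0246; adjusted p = 0.947 with an estimated correlation). The smooth muscle myosin Myh11 stood at 2738 ± 3628 CPM in vehicle and 57.3 ± 19.3 CPM in relapse tumours (-5.58 ± 1.25, adjusted p = 0.0088), and smooth muscle actin Acta2 fell by 3.90 ± 0.92 (adjusted p = 0.0106). These values rested on vehicle 2, 6 and 7, in which Cnn1 was at 852, 808 and 400 CPM; it was at 6.1 CPM or lower in the other vehicle tumours. Without those tumours the list's median was 0.15 (adjusted p = 0.718) and Cnn1 was at 0.37 (adjusted p = 0.745). The basal keratin gene Krt14 was named after its values were seen. It was at 85.0, 172 and 342 CPM in vehicle 2, 6 and 7. In the other vehicle tumours it was higher, at 771 to 2507 CPM. The basal keratin gene Krt5, also named after its values were seen, was not raised in vehicle 2, 6 and 7. It was at 230, 323 and 421 CPM there and at 191 to 825 CPM in the other vehicle tumours.

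Fibroblast markers had a median of 0.71 over 17 genes, of which 4 rose (5 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00137; adjusted p = 0.947 with an estimated correlation). They included the microfibril protein Mfap5 (1.94 ± 0.31, adjusted p = 0.00156) and the matrix protein Fbln1 (1.61 ± 0.32, adjusted p = 0.00473). Adipocyte markers had a median of 1.33 over 15 genes, of which 1 rose, the hormone-sensitive lipase Lipe (1.33 ± 0.32, adjusted p = 0.0122; also 1 adjusted over the list alone). Their camera adjusted p was 0.00815, and it was an adjusted p = 0.947 with an estimated correlation. Cell cycle genes had a median of 0.19 over 25 genes and passed the camera test (adjusted p = 0.042; adjusted p = 0.947 with an estimated correlation), although edgeR called 0 of them, also when adjusted over the list alone. Their median was -0.19 (adjusted p = 0.0219) without vehicle 2, 6 and 7, whose cell cycle scores were -1.18, -1.47 and -1.04. That call too was lost with an estimated correlation, with which no list passed in that fit (lowest adjusted p = 0.0637). Without those tumours the fibroblast median was 1.09 (adjusted p = 3.72e-07; adjusted p = 0.58 with an estimated correlation), the adipocyte median 0.96 (adjusted p = 0.0371; adjusted p = 0.806 with an estimated correlation) and Lipe at 0.96 (adjusted p = 0.112). With counts summed per title code the adipocyte list (adjusted p = 0.117), the cell cycle list (adjusted p = 0.221) and Lipe (adjusted p = 0.0931) lost their calls.

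Nf1, which encodes a GTPase-activating protein for RAS (Entrez gene 18015, chromosome 11, 79339590 to 79581609), was at 336 ± 89.4 CPM in vehicle and 259 ± 30.1 CPM in relapse tumours. Its log2 fold change of -0.38 (95% confidence interval -0.76 to 0.0042; adjusted p = 0.187) did not pass the test, and 6 of 7 relapse tumours lay below the vehicle median. Without vehicle 2, 6 and 7, in which Nf1 was at 460, 450 and 368 CPM, it was at -0.05 (adjusted p = 0.915). Among the other genes fixed for every comparison, the following did not pass the test. Pik3ca was at 0.37 (interval -0.22 to 0.96; adjusted p = 0.419), the cyclin gene Ccnd1 at -0.60 (-1.04 to -0.15; adjusted p = 0.0753; 0.0453 without vehicle 2 and 0.0292 without vehicle 3) and the ERK phosphatase gene Dusp6 at 0.45 (-0.45 to 1.36; adjusted p = 0.539). The proliferation marker Mki67 was at 0.45 (-0.31 to 1.201; adjusted p = 0.455) and Pik3ip1, which encodes a PI3K inhibitor, at 0.42 (-0.41 to 1.26; adjusted p = 0.535). With vehicle 2, 6 and 7 left out, Pik3ip1 was at 1.60 (adjusted p = 0.0234).

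edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1772 of 15792 genes between relapse and vehicle tumours, 856 higher and 916 lower, and 4338 genes had an unadjusted p under 0.05. With upper quartile scaling the calls were 953 higher and 673 lower. The count was 1160 without vehicle 2, 1156 without vehicle 6 and 527 without vehicle 2, 6 and 7 (314 higher and 213 lower). It was 955 with counts summed per title code (311 higher and 644 lower), and 180 with those sums and without the 3 vehicle tumours. With 1 tumour per code, which also leaves out those 3 tumours, it was 12. In the fit without the 3 vehicle tumours camera called 0 lists with an estimated correlation (lowest adjusted p = 0.0637). Of the genes not called, 67.1% had a 95% interval within 2-fold in both directions. The remaining 20 tested lists did not pass the camera test, with adjusted p from 0.0557 for antigen presentation to 0.931 for nerve and Schwann cell markers. They were ERK pathway output, RAS and PI3K negative regulators, glycolysis, oxidative phosphorylation, interferon response, mesenchymal transition, WNT and NOTCH targets, hypoxia and angiogenesis, immediate early and heat shock genes, and markers of luminal, milk and alveolar, squamous, endothelial, macrophage, neutrophil, T and NK, dendritic and mast, and erythroid cells. The squamous, neutrophil and mesenchymal transition lists had medians of -0.60, -0.04 and -0.13 and a camera direction of up, and the interferon and T and NK cell lists medians of 0.0051 and 0.16 and a direction of down. Markers of B and plasma cells, with 2 measured genes, were not tested.

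**Figure D2:**
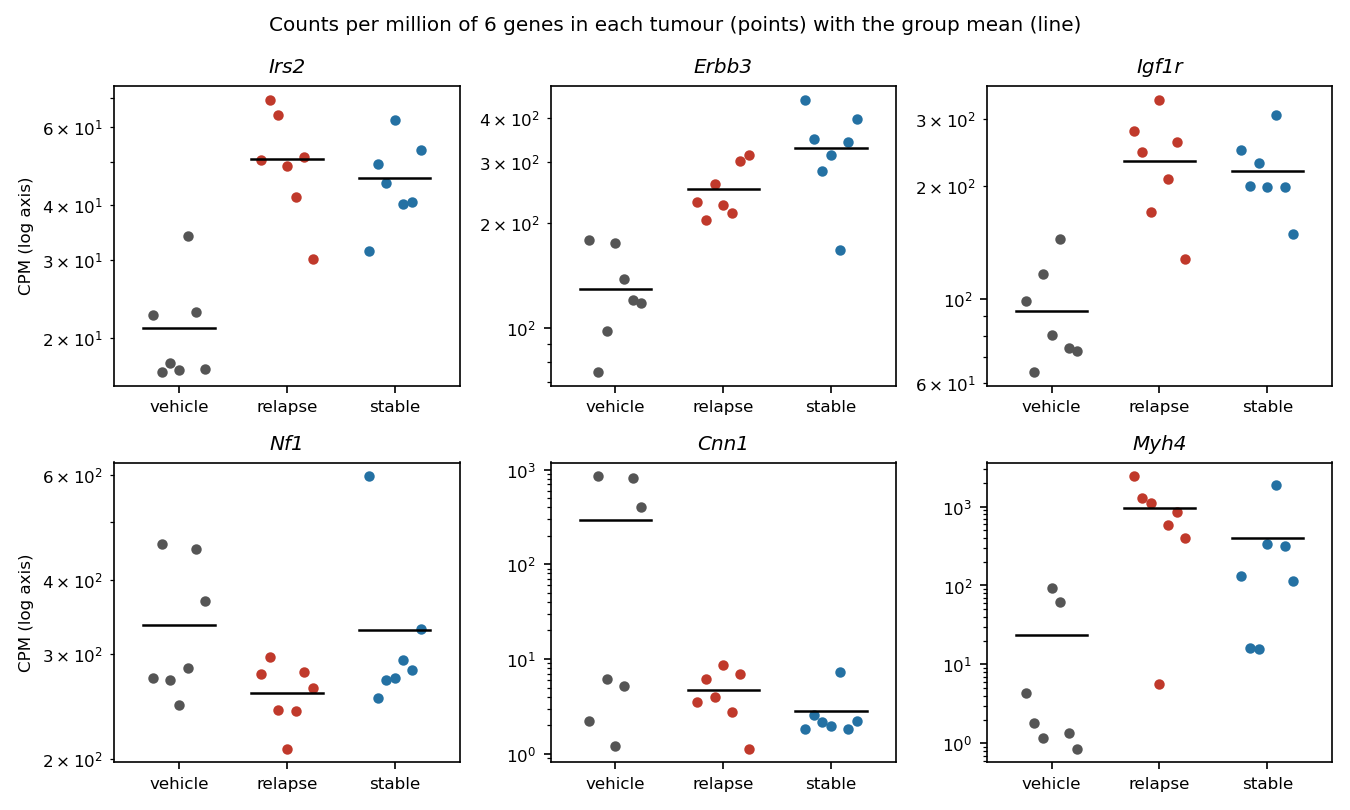
CPM of 6 genes on a log axis in each tumour (points) of the vehicle, relapse and stable groups, with the group mean as a line. Erbb3 has group means of 130, 250 and 330 CPM and Nf1 of 336, 259 and 329 CPM; 3 vehicle tumours hold the high values of Cnn1.

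Stable against vehicle asks which transcripts differed in tumours labelled stable under BYL719. The stress-induced Sesn3, a FOXO target and regulator of mTORC1, rose from 50.9 ± 5.48 to 117 ± 36.7 CPM (log2 fold change 1.203 ± 0.18, edgeR adjusted p = 0.000492, n = 7 each), with 7 of 7 stable tumours above the vehicle median. Erbb3, a receptor of the EGF receptor family, rose from 130 ± 38.4 to 330 ± 90.4 CPM (1.35 ± 0.20, adjusted p = 0.000614). The cyclin gene Ccnd1 fell from 309 ± 106 to 161 ± 35.5 CPM (-0.94 ± 0.21, adjusted p = 0.00823). Of the genes with a standard error in this comparison, Pfkp and Cnn1 lay beyond the vehicle median in 6 of 7 stable tumours, and the others in 7 of 7.

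PI3K feedback genes and FOXO targets had a median of 0.71, and 11 of 22 rose while 0 fell in edgeR's test (13 and 0 adjusted over the list alone). Irs2 (1.13 ± 0.20, adjusted p = 0.0014), Insr (0.49 ± 0.11, adjusted p = 0.00929) and the cyclin gene Ccng2 (1.17 ± 0.19, adjusted p = 0.000959) were among them. The camera adjusted p was 1.73e-06, and this list alone kept its call, at an adjusted p = 0.0217 with an estimated correlation. With that correlation the call was lost with counts summed per title code (adjusted p = 0.226) and without stable 1 (adjusted p = 0.0989). The median was 0.84 (adjusted p = 1.08e-09; adjusted p = 0.0104 with an estimated correlation) without vehicle 2, 6 and 7, and Insr lost its call with counts summed per title code (adjusted p = 0.0523).

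Cholesterol and fatty acid synthesis genes had a median of -0.83 over 26 genes, of which 17 fell and 0 rose (20 and 0 adjusted over the list alone; camera adjusted p = 1.65e-08; adjusted p = 0.688 with an estimated correlation). Fdft1 (-0.88 ± 0.13, adjusted p = 0.000631), Sc5d (-0.80 ± 0.14, adjusted p = 0.00171) and the fatty acid desaturase Scd2 (-0.95 ± 0.19, adjusted p = 0.00318) fell. Glycolysis genes had a median of -0.38 over 20 genes, of which 3 fell (3 adjusted over the list alone; camera adjusted p = 0.00614; adjusted p = 0.855 with an estimated correlation). The glucose transporter Slc2a1 fell by 0.96 ± 0.29 (adjusted p = 0.033) and the phosphofructokinase Pfkp by 0.91 ± 0.25 (adjusted p = 0.0202). Stable 5 had the lowest score of all tumours for glycolysis (-0.96), cholesterol and fatty acid synthesis (-0.788) and oxidative stress (-0.757). Its oxidative phosphorylation (-0.675) and ATF4 (-0.664) scores were the lowest too. Its fibroblast (1.55), T and NK cell (1.72) and dendritic and mast cell (2.52) scores were the highest. List tests without stable 5 were not run. Of 23 oxidative stress and glutathione genes, 4 fell (5 adjusted over the list alone), among them Nqo1 (-1.70 ± 0.35, adjusted p = 0.00457), with a median of -0.33 (camera adjusted p = 0.00192; adjusted p = 0.759 with an estimated correlation). With vehicle 2, 6 and 7 left out the medians of the cholesterol, glycolysis and oxidative stress lists were -0.99, -0.48 and -0.35, each past the camera test. Each of these calls was lost with an estimated correlation (adjusted p = 0.145, 0.628 and 0.628). In that fit Nqo1 (-0.97, adjusted p = 0.0886) and Pfkp (-0.61, adjusted p = 0.178) lost their calls. Pfkp also lost its call without vehicle 2 (adjusted p = 0.0656) or vehicle 7 (0.0656), and Slc2a1 without vehicle 3 (0.0627), 5 (0.0514) or 7 (0.0555) or stable 3 (0.0608), 5 (0.0522) or 6 (0.0657). With summed counts Scd2 (adjusted p = 0.0538) and Slc2a1 (adjusted p = 0.156) lost theirs.

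Basal and myoepithelial markers had a median of -2.57 over 14 genes, of which 6 fell (11 adjusted over the list alone; camera adjusted p = 0.0012; adjusted p = 0.759 with an estimated correlation). Cnn1 was at 2.84 ± 1.99 CPM in stable tumours (-6.71 ± 1.31, adjusted p = 0.00314). Without vehicle 2, 6 and 7 the list's median was -0.34 (adjusted p = 0.0503) and Cnn1 was at -0.37 (adjusted p = 0.715). Skeletal muscle markers had a median of 3.16 over 13 genes, of which 7 rose (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0012; adjusted p = 0.855 with an estimated correlation). Myh4 was at 404 ± 667 CPM in stable tumours (4.10 ± 1.32, adjusted p = 0.0413) and at 2.73 (adjusted p = 0.117) without stable 5. It also lost its call without vehicle 1 (adjusted p = 0.061), 2 (0.0759), 3 (0.0624), 6 (0.0743) or 7 (0.0714) or stable 4 (0.0567) or 6 (0.0561). In edgeR's test 0 of the 13 markers were called with counts summed per title code and 0 without vehicle 2, 6 and 7, although the list's medians of 3.50 (adjusted p = 0.00274) and 2.496 (adjusted p = 0.00512) passed the camera test. With an estimated correlation these were an adjusted p = 0.917 and an adjusted p = 0.811. The muscle scores differed by 2.64 between the group means (two-sided exact permutation p = 0.00816; Benjamini-Hochberg adjusted over 3 comparisons 0.0122). Within classes of the digit in the last part of the title, the difference was 2.04 (exact permutation p = 0.0385, adjusted 0.0578). Both tests exchanged single tumours, some of which share a title code. The 8 divisions that keep codes whole are too few for a p under 0.05.

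Fibroblast markers had a median of 0.53 over 17 genes, of which 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0488; adjusted p = 0.867 with an estimated correlation). Mfap5 (1.83 ± 0.31, adjusted p = 0.00118) and the cell surface glycoprotein Thy1 (1.56 ± 0.37, adjusted p = 0.0104) were among them. The list lost its call with the replicate block (adjusted p = 0.062) and with DESeq2 size factors (0.0514), and Thy1 with summed counts (0.0555) and without vehicle 2, 6 and 7 (1.31, adjusted p = 0.0856). Cell cycle genes had a median of 0.43 over 25 genes (camera adjusted p = 0.0252; adjusted p = 0.867 with an estimated correlation), and edgeR called 0 of them, also when adjusted over the list alone. The cell cycle call was lost without stable 1 (adjusted p = 0.352), whose cell cycle score of 1.32 was the highest, and with summed counts (adjusted p = 0.648), and the median was -0.02 (adjusted p = 0.0607) without vehicle 2, 6 and 7. Leaving out stable 1 added the oxidative phosphorylation (median -0.23, adjusted p = 0.00723), ATF4 (-0.31, adjusted p = 0.00723) and antigen presentation (-0.48, adjusted p = 0.0314) lists, and summing counts the ATF4 (-0.26, adjusted p = 0.0254) and squamous (-0.86, adjusted p = 0.0442) lists. In neither setting was a list called with an estimated correlation (lowest adjusted p = 0.0989 and 0.226). The remaining 21 tested lists did not pass, with adjusted p from 0.0529 for macrophage markers to 0.927 for T and NK cell markers. Among them, the neutrophil list had a median of -0.52 and a camera direction of up, and the T and NK cell and the immediate early and heat shock lists medians of 0.23 and 0.03 and a direction of down.

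Nf1 was at 329 ± 120 CPM in stable tumours, a log2 fold change of -0.03 (95% confidence interval -0.42 to 0.35; adjusted p = 0.923). Stable 1 had 597 CPM of Nf1 and the other stable tumours 253 to 331 CPM. The value was -0.24 (adjusted p = 0.225) without stable 1, and it turned to between 0.0013 and 0.081 without vehicle 2, 6 or 7 or stable 2, 3, 4 or 6. Without vehicle 2, 6 and 7 it was at 0.31 (adjusted p = 0.367). Pik3ca was at 0.67 (interval 0.07 to 1.26; adjusted p = 0.115), Dusp6 at 0.63 (-0.28 to 1.54; adjusted p = 0.334), Mki67 at 0.53 (-0.22 to 1.29; adjusted p = 0.327) and Pik3ip1 at 0.53 (-0.31 to 1.37; adjusted p = 0.383). Dusp6 was at 535 CPM in stable 1 and 62.8 to 106 CPM in the other stable tumours, and its value turned to -0.17 (adjusted p = 0.697) without stable 1. Pik3ip1 was at 1.71 (adjusted p = 0.00938) without vehicle 2, 6 and 7.

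edgeR called 2378 of 15792 genes between stable and vehicle tumours, 1090 higher and 1288 lower, with 4919 at an unadjusted p under 0.05. With upper quartile scaling the balance turned, to 1294 higher and 1032 lower. The count was 1496 without vehicle 2, 1470 without vehicle 6, 847 without vehicle 2, 6 and 7, and 964 (499 higher and 465 lower) when only these 2 groups were fitted. It was 592 with counts summed per title code (210 higher and 382 lower), and 172 with those sums and without the 3 vehicle tumours. With 1 tumour per code, which also leaves out those 3 tumours, it was 27. In the fit without the 3 vehicle tumours camera called 1 list with an estimated correlation, that of PI3K feedback genes and FOXO targets (adjusted p = 0.0104). Of the genes not called, 64.7% had a 95% interval within 2-fold.

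**Figure D3:**
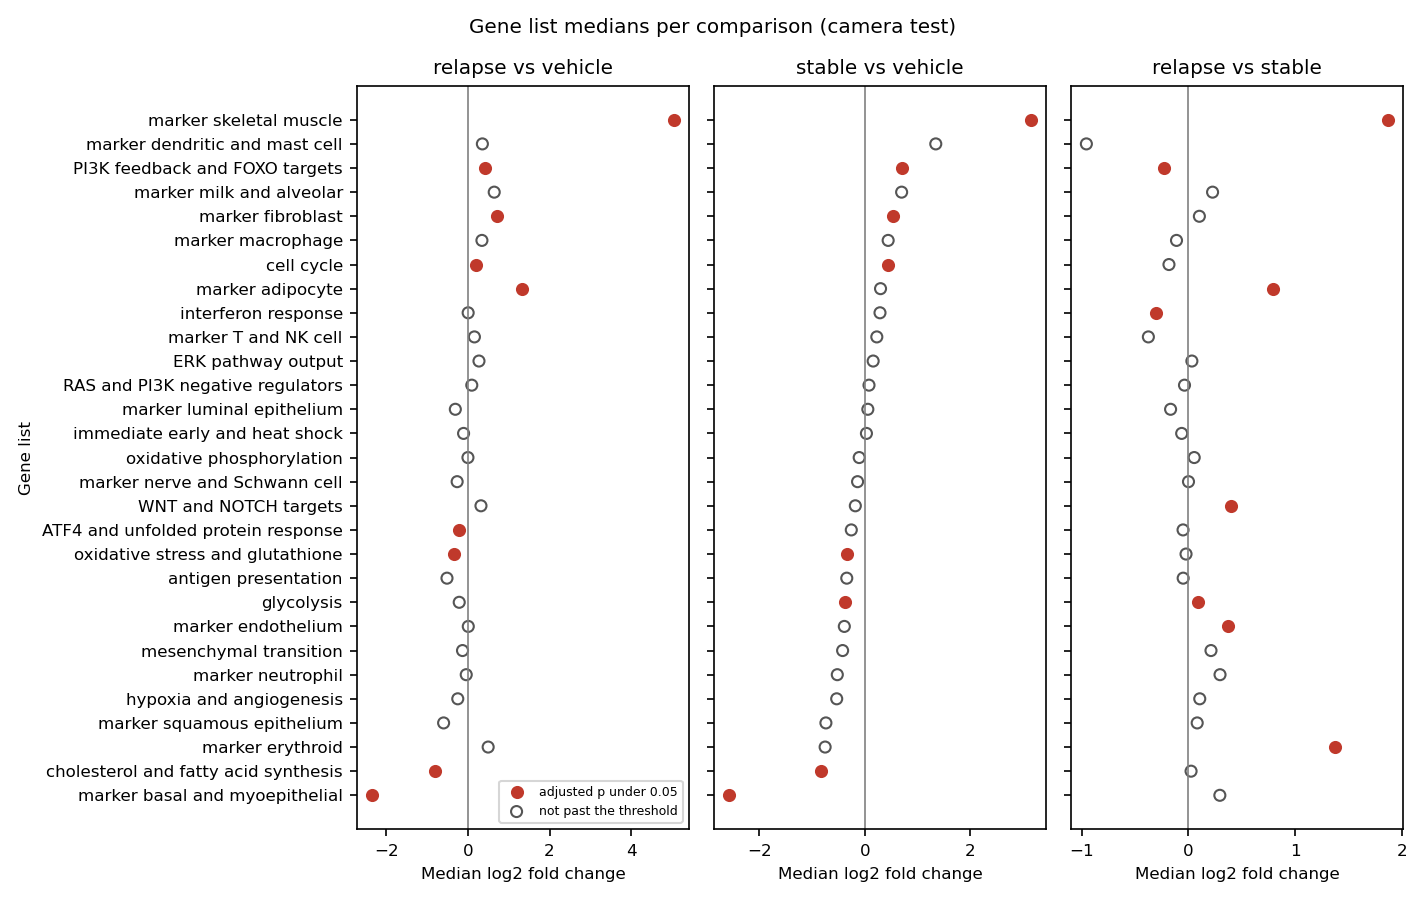
Median log2 fold change of 29 gene lists in the 3 comparisons, with filled points for a camera adjusted p under 0.05 (preset correlation) and open points otherwise; lists are ordered by stable against vehicle. Skeletal muscle markers lie at 5.05, 3.16 and 1.87 and basal and myoepithelial markers at -2.34, -2.57 and 0.29.

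Both BYL719 groups were compared with the same vehicle tumours. Genes called higher in both numbered 547, against 59.1 for independent lists of these sizes, and genes called lower in both numbered 716, against 74.7. Erbb3, Irs2, Sc5d, Fdft1, Nqo1 and Mfap5 were among them. Simulated unchanged groups against the shared vehicle tumours had on average 0 shared calls by edgeR, a correlation of log2 fold changes across genes of 0.50 and a covariance of 0.0687 (10 simulations). The observed correlation was 0.886 and the observed covariance 0.637, so that the difference of the covariances was 0.569; genes are not independent replicates. The vehicle tumours were then divided by title code into 5 to 7 and 1 to 4, so that each comparison had its own controls. In both, 110 genes were called higher and 168 lower (correlation 0.718, covariance 0.7235). The other way round there were 82 and 141 (correlation 0.683, covariance 0.7096). Both sets of controls hold tumours that stand apart, vehicle 6 and 7 in one and vehicle 2 in the other. With these 3 left out, a choice made after seeing the data, 173 genes were higher and 153 lower in both, against the same 4 controls. The correlation was 0.84 and the covariance 0.464. With 2 controls for each comparison, vehicle 3 and 4 for relapse and 1 and 5 for stable tumours, edgeR called 10 higher and 5 lower in both (correlation 0.55, covariance 0.392). The other way round it called 0 in both (correlation 0.533, covariance 0.389). At an unadjusted p under 0.05, 408 were higher and 352 lower in both, and other tools were not run.

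Relapse against stable asks whether tumours with the 2 outcomes under BYL719 differed. Skeletal muscle markers were higher in relapse tumours by a median log2 fold change of 1.87 over 13 genes, erythroid markers by 1.37 over 4 genes and endothelial markers by 0.37 over 14 genes. Interferon response genes were lower by a median of -0.30 over 21 genes (0.09 without stable 1), and PI3K feedback genes and FOXO targets by -0.23 over 22 genes. In these lists edgeR called 0 members over all genes, and no list passed with an estimated correlation (lowest adjusted p = 0.346 with an estimated correlation; exact permutation p = 0.0717 for the muscle scores). The largest named difference was that of Myh7, the slow myosin heavy chain of muscle, at 97.8 ± 88.1 CPM in relapse and 0.617 ± 0.491 CPM in stable tumours (log2 fold change 7.31 ± 1.31, n = 7 each). Its adjusted p of 0.125 did not pass the test, and 6 of 7 relapse tumours lay above the stable median. Nf1 was at 259 ± 30.1 and 329 ± 120 CPM (-0.35, 95% confidence interval -0.73 to 0.04, adjusted p = 0.99), and the difference was -0.14 without stable 1.

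edgeR called 0 of 15792 genes between relapse and stable tumours, with 751 at an unadjusted p under 0.05. limma voom called 0 with sample quality weights (1881 unadjusted) and 0 with the title code as a random effect (774 unadjusted). DESeq2 called 6 genes, all higher in relapse tumours: the muscle genes Myh7 (adjusted p = 5.65e-08), Myh6, Myl2, Tnnc1 and Ankrd2, and the small heat shock gene Cryab (adjusted p = 0.0452). Without relapse 4 edgeR called 4 genes, Myh7, Myh6, Myl2 and Ankrd2, and without stable 5 it called 1, the muscle gene Fhl1 (2.46, adjusted p = 0.0223). These genes were named after their values were seen. Without stable 5, 1430 genes had an unadjusted p under 0.05. Of the 15792 genes, 72.4% had a 95% interval within 2-fold. In simulated data of this size edgeR recovered 46% of 200 genes changed 2-fold and 87% of 200 changed 4-fold in this comparison.

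The camera test passed for skeletal muscle (adjusted p = 2.99e-09), endothelium (0.000252), erythroid (0.000616), interferon response (0.0033), PI3K feedback and FOXO targets (0.00379), adipocyte (median 0.79, 0.00762), WNT and NOTCH targets (median 0.40, 0.0319) and glycolysis (median 0.09, 0.0371). With an estimated correlation each call was lost (adjusted p = 0.346 or higher). Within these lists edgeR called 0 members over all genes; adjusted over the list alone, 3 skeletal muscle and 4 erythroid genes were higher and 0 of the others were called. Among the members, Sesn3 was at -0.49 (interval -0.85 to -0.12; adjusted p = 0.99), the alpha globin gene Hba-a2 at 1.54 (0.54 to 2.55; adjusted p = 0.99) and the chemokine gene Cxcl10 at -3.52 (-5.68 to -1.37; adjusted p = 0.99). Cxcl10 was at 74.1 CPM in stable 1 and at 1.91 CPM or lower in the other stable tumours. Without stable 1 the median of the interferon list turned to 0.09 (adjusted p = 0.398) and the WNT and NOTCH list an adjusted p = 0.354, while the oxidative phosphorylation (median 0.22, adjusted p = 1.88e-07) and ERK output (median 0.24, adjusted p = 0.0279) lists passed. Summing counts per title code added oxidative phosphorylation (0.10, adjusted p = 0.0178), luminal markers (-0.19, adjusted p = 0.0213) and dendritic and mast cell markers (-1.44, adjusted p = 0.0213). Stable 5 had the highest dendritic and mast cell score, at 2.52. With an estimated correlation no list passed in either setting (lowest adjusted p = 0.439 and 0.747). The muscle scores of the groups differed by 2.20 (two-sided exact permutation p = 0.0717, which is also its Benjamini-Hochberg value over 3 comparisons). The remaining 21 tested lists did not pass, with adjusted p from 0.0583 to 0.91; the oxidative stress list, at -0.02, and the ATF4 list, at -0.05, had a camera direction of up.

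The fixed genes named here did not pass the test between relapse and stable tumours. Irs2 was at 0.14 (interval -0.26 to 0.54), Insr at -0.09 (-0.33 to 0.14), Erbb3 at -0.40 (-0.81 to 0.02) and Ccnd1 at 0.35 (-0.10 to 0.79). Pik3ca was at -0.29 (-0.88 to 0.30), Dusp6 at -0.18 (-1.08 to 0.73), Mki67 at -0.09 (-0.84 to 0.67) and Pik3ip1 at -0.11 (-0.94 to 0.73). Dusp6 turned to 0.62 without stable 1, Mki67 to 0.011 without relapse 1, and Pik3ip1 to 0.0024 without relapse 5 and 0.049 without stable 6. Among the genes with the lowest p but not past the threshold, Tmem87a (-0.36 ± 0.09) and Tmem87b (-0.29 ± 0.07), which are related in sequence, and Hmgb1 (-0.41 ± 0.11) were lower in 7 of 7 relapse tumours than the stable median (adjusted p = 0.984 each). Lsm8, a U6 snRNA-binding protein gene on chromosome 6 (18848635 to 18854052), was at -3.81 ± 1.01 (adjusted p = 0.984). Its value rested on stable 1, with 1481 CPM against 10.1 to 21.8 CPM in the other stable tumours.

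Stable 1 also had high counts of genes next to Lsm8. From 15720566 to 21879596 on chromosome 6, 9 of 11 genes were more than 1 log2 unit above their median over all tumours, with a median of 4.48 for the 11 genes. The receptor tyrosine kinase gene Met (chromosome 6, 17463349 to 17573980) was at 13690 CPM in stable 1, and its median and highest value in the other 20 tumours were 248 and 413 CPM. Capza2, an actin capping protein gene, was at 11520 CPM (median elsewhere 232) and Tes, a focal adhesion gene, at 5885 CPM (93.6). Cftr and Cttnbp2, within the same stretch, were at 1.87 and 2.39 CPM, below their medians of 13.7 and 18.3 CPM in the other tumours, and Cav1, at 348 CPM, was below its highest value elsewhere of 929 CPM. The region was chosen after its values were seen.

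**Figure D4:**
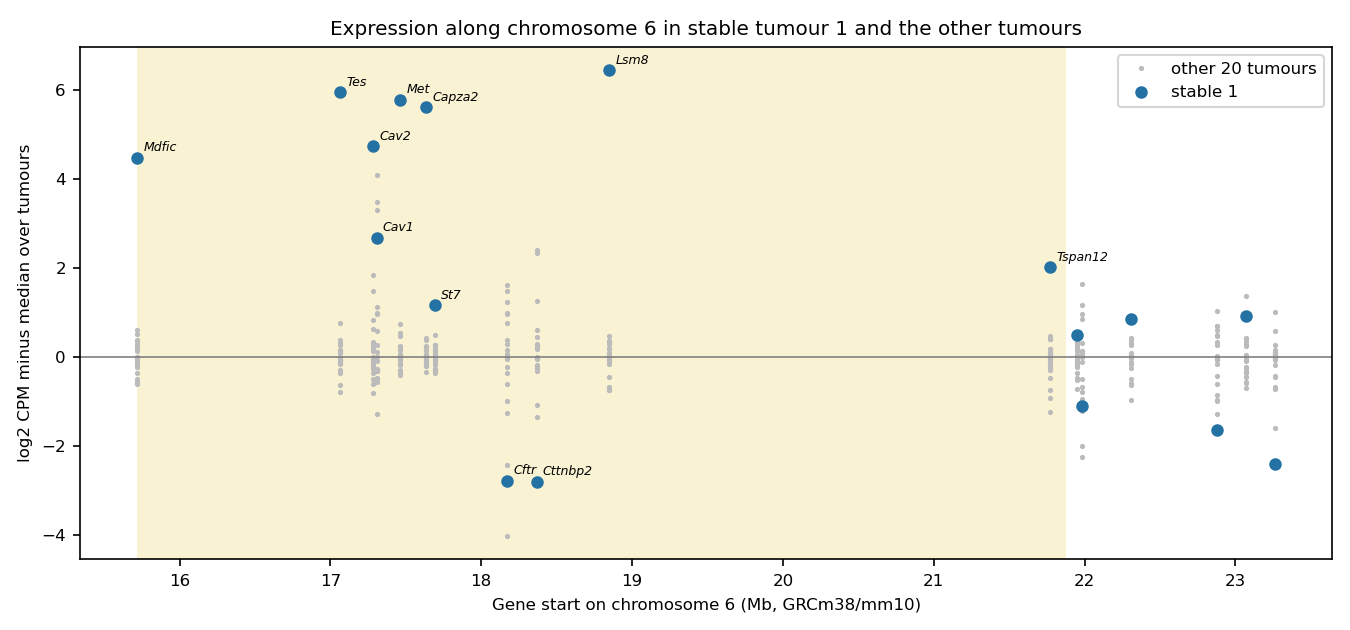
log2 CPM minus the median over tumours for genes by their start on chromosome 6 (GRCm38), in stable 1 (large points) and the other 20 tumours (small points); the shaded stretch runs from 15720566 to 21879596. In stable 1, 9 of the 11 genes in the shaded stretch lie more than 1 above the median, and Cftr and Cttnbp2 lie at -2.78 and -2.80.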

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

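All tests in this part concern patterns that had been seen in the results. For the thinning of the libraries and the random gene orders the predictions were written before the test, and for the other explanations after. Single tumours far from the other 6 of their group were sought among the CPM of 126 named genes and the total counts by Dixon's test, and 41 of these 381 groups held such a tumour; chance gives about 1 in 20 groups, and genes that move together are not independent.

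In relapse 4, 15 values were far below those of the other relapse tumours, all of muscle genes. In CPM they were Acta1 169, Casq2 1.75, Ckm 0.399, Myh2 2.49, Myh4 5.59, Myh8 1.496, Myl1 0.0998, Mylpf 1.60, Myom2 0.199, Myot 0.199, Ppp1r3a 0.0998, Tcap 0.0998, Tnnc2 0.449, Tnnt3 1.496 and Xirp2 3.54. Elsewhere in the relapse group Ckm was at 70.8 to 344 CPM. In relapse 1, Mcm7 (45.7 CPM) and Mki67 (505 CPM), genes of proliferating cells, were low. In relapse 2, the WNT pathway genes Lef1 (112 CPM, others 5.17 to 12.2), Nkd1 (221 CPM, others 7.68 to 21.7) and Znrf3 (197 CPM, others 39.6 to 76.6) were high. In relapse 5, Mfap5 was low at 7.98 CPM.

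In stable 1, 12 values were far from the other stable tumours. High in CPM were Abca13 217, Atf4 404, Ccng2 253, Cxcl10 74.1, Dusp6 535, Ifit2 187, Kng2 131, Lsm8 1481 and Nf1 597, and low were Cdkn1b 125, Flt1 27.2 and Pfkfb3 37.3. Stable 5 was high in Cnn1 (7.32 CPM), Cpt1b (11.7 CPM) and Gria4 (8.33 CPM). Among vehicle tumours, Cryab was high in vehicle 2 (68.8 CPM), Fabp4 in vehicle 3 (380 CPM) and Pfkfb3 in vehicle 7 (224 CPM), where Acta1 (132 CPM) and Hmgb1 (13.4 CPM) were low.

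As a list, basal and myoepithelial genes, such as Cnn1 and Myh11, were lower in both BYL719 groups. Each list call was lost with an estimated correlation. The basal keratin gene Krt14 went the other way in vehicle 2, 6 and 7, at 85.0, 172 and 342 CPM. It was at 771 to 2507 CPM in the other vehicle tumours. Krt5, another basal keratin gene, was at 230 to 421 CPM in vehicle 2, 6 and 7, within the 191 to 825 CPM of the other vehicle tumours. The list difference may be carried by vehicle 2, 6 and 7. Without them the list had an adjusted p of 0.718 in relapse against vehicle and 0.0503 in stable against vehicle. With every library thinned to 13337848 counts the median in relapse against vehicle was -2.36. Thinning hardly alters CPM ratios of highly expressed genes, so it cannot decide on depth. Vehicle 1, 3, 4 and 5, with 21226564 to 22317907 counts, had basal scores of 0.779 or lower. Vehicle 7, with 21043399 counts, had 2.25, which argues against depth as the whole cause. The title code as the whole cause is argued against too: vehicle 5, with the code of vehicle 6 and 7, had a basal score of 0.0882. Vehicle 1, with the code of vehicle 2, had -0.513. Against the other 4 vehicle tumours the neutrophil score was changed by -3.5 ± 0.62 (SE), the endothelial score by 1.16 ± 0.29 and the nerve and Schwann cell score by 1.16 ± 0.18. Of 10 other cell type lists, 2 were higher and 1 was lower by more than 3 SE. Other cell types need not change together, so these scores do not decide whether the 3 tumours held a lower share of tumour epithelium. A different tumour type and tissue sampled beside the tumour stay open and were not tested.

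Skeletal muscle genes, such as Myh4 and Ckm, were higher in relapse than in vehicle tumours (list adjusted p = 0.442 with an estimated correlation). The digit in the last part of the title was taken as a gland position. It was tested by permuting only within digits 1 to 3 and within 4 and 5. The score difference of 4.55 had an exact permutation p of 0.00476 (0.0143 adjusted over 3 comparisons). If tumours with 1 title code are independent, this argues against position as the whole cause. For stable against vehicle the exact permutation p was 0.0385 (0.0578 adjusted). The permutations exchanged single tumours and did not keep title codes whole. Muscle fibres carried over with the tumour cannot be told apart from muscle genes expressed in the tumour: in each relapse tumour with a score above 0, 13 of 13 genes lay above their mean, but the score that picks these tumours is made of the same genes. Median levels of Myh4 were 850 CPM in relapse, 133 CPM in stable and 1.83 CPM in vehicle tumours, and Acta1 was above 10 CPM in 7 of 7 vehicle tumours. Growth of the tumours into muscle and differences in dissection between the groups stay open.

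The raised genes on chromosome 6 in stable 1, among them Met, Capza2 and Lsm8, had a highest running median of 4.74, and in 1000 random gene orders the highest was 2.02 (permutation p = 0.001, the smallest these orders can give). Random orders do not keep neighbours that are regulated together, and 14 other tumours had a running median over 1, the highest 2.44. Stable 1 and this region were picked after their values were seen. A regional gain of copies may explain the pattern and stays open: 9 of the 11 genes were raised, but the stretch was drawn from its first to its last raised gene, and Cftr and Cttnbp2 within it were not raised. No DNA measurements were seen, and no biological explanation was tested, since the design has no group for it.

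Chance assignment was tested by other divisions of the 14 tumours of a comparison into 7 and 7, in fits of all 21 tumours. With tumours of 1 title code kept together, the real groups of relapse against vehicle gave 1772 genes. The highest other of 78 divisions gave 97, and 1 division (the real one) gave as many as the real groups. This argues against chance but does not exclude it, since the vehicle group held only 3 codes. For stable against vehicle such divisions are too few, at 8, for a share under 0.05 (2378 genes, highest other 0 by edgeR). Among 100 divisions that exchange single tumours, which possibly share an animal, 1 (the real one) gave as many in either comparison, with a highest other of 810 and 2091; these and the division by code with 97 genes had vehicle 2, 6 and 7 on the same side, which points to a structure of the samples. For relapse against stable the divisions decide nothing, since edgeR called 0 genes (751 at an unadjusted p under 0.05; DESeq2 called 6) and so 100 of 100 gave as many, the highest other 1.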

How the results depend on the processing

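Fits without vehicle 2, 6 and 7, alone or with summed counts, were chosen after seeing the data, as were list tests without stable 1 and, with an estimated correlation, those without stable 1, without the 3 vehicle tumours and with summed counts. Fdft1 kept its calls in both comparisons with vehicle under every alternative run except the added fold limit, an absolute log2 fold change above 1, which its changes of -0.70 and -0.88 do not reach.

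The 1772 genes of relapse against vehicle became 987 with a replicate block, 955 with counts summed per title code, 12 with 1 tumour per code, 527 without vehicle 2, 6 and 7, 180 without them and with summed counts, and 976 with an absolute log2 fold change above 1. Leaving out 1 tumour gave 1156 (without vehicle 6) to 2060, and 1160 without vehicle 2. The 2378 genes of stable against vehicle became 964 with only these 2 groups, 1251 with a replicate block, 592 summed, 27 with 1 tumour per code, 847 without vehicle 2, 6 and 7, 172 without them and summed, and 1033 with the fold limit. Leaving out 1 tumour gave 1470 (without vehicle 6) to 3272 (without stable 1), and 1496 without vehicle 2. For relapse against stable, where edgeR called 0 genes (751 at an unadjusted p under 0.05), DESeq2 called 6, and leaving out 1 tumour gave 0 to 4 (4 without relapse 4, 1 without stable 5). The fold limit lowers a count by its construction. The setting with 1 tumour per code also leaves out vehicle 2, 6 and 7. Apart from the fold limit, the cause was not tested. The replicate numbers do not pair the tumours: same-numbered tumours had correlations of -0.258 to 0.358, and 3 of 21 were above 0.1.

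The lists called, 9, 8 and 8 in the 3 comparisons, became 0, 1 and 0 with an estimated correlation, and 14 in relapse against vehicle without vehicle 2, 6 and 7 (0 there with an estimated correlation). With summed counts the ATF4 (adjusted p = 0.0696), cell cycle (0.221) and adipocyte (0.117) lists of relapse against vehicle lost their calls, as did cell cycle in stable against vehicle (0.648). The sums added the ATF4 (0.0254) and squamous (0.0442) lists in stable against vehicle, and oxidative phosphorylation (0.0178), luminal (0.0213) and dendritic and mast cell markers (0.0213) in relapse against stable. With an estimated correlation 0 lists were called on the sums (lowest adjusted p = 0.226) and 0 without stable 1 (lowest adjusted p = 0.0989). In stable against vehicle the fibroblast list lost its call with the replicate block (0.062) and DESeq2 size factors (0.0514). In relapse against stable the block added the oxidative phosphorylation and luminal (0.0468 each) and basal (0.0462) lists, and the size factors the basal list (0.0436); these 2 settings were not run with an estimated correlation. Leaving out vehicle 2, 6 and 7 added squamous (2.13e-05), neutrophil (0.00874), hypoxia (0.0215), ATF4 (0.0366) and oxidative phosphorylation (0.0474) lists in stable against vehicle, and basal (0.00693), mesenchymal (0.043) and luminal (0.0448) lists in relapse against stable, each lost with an estimated correlation (adjusted p = 0.628 or higher). The cell cycle median reversed without vehicle 2, 6 and 7, to -0.19 in relapse (adjusted p = 0.0219) and -0.0199 in stable tumours (adjusted p = 0.0607).

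Log2 fold changes of some named genes lower than in vehicle reversed. In relapse against vehicle with 1 tumour per code, Cnn1 was at 0.054, Myh11 at 0.035, Apod at 0.32 and Acta2 at 0.028. Without vehicle 2, 6 and 7, Gria4 was at 0.14, Cnn1 at 0.37, Myh11 at 0.36, Apod at 0.54, Mylk at 0.20 and Acta2 at 0.28, and with summed counts as well, Gria4 at 0.10, Cnn1 at 0.33, Myh11 at 0.34, Apod at 0.38, Mylk at 0.15 and Acta2 at 0.31. In stable against vehicle with 1 tumour per code, Gria4 was at 0.99, Maob at 0.15 and Apod at 0.36. Without the 3 vehicle tumours, Myh11 was at 0.059, Gria4 at 0.80, Maob at 0.24 and Apod at 0.42, and with summed counts as well, Myh11 at 0.38, Gria4 at 1.2, Maob at 0.54, Apod at 0.49 and Mylk at 0.0055. These genes were high in vehicle 2, 6 and 7, and each of these settings leaves those tumours out. Beyond that the cause was not tested.

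Over all alternatives, the named genes of relapse against vehicle kept their side of the threshold in 1488 fits. They lost the threshold in 269, gained it in 20 and reversed in 16. For stable against vehicle these were 1408, 361, 13 and 12, and for relapse against stable 1245, 0, 3 and 0. In relapse against stable edgeR called 0 genes, so that none could lose the threshold. Fits leaving out 1 tumour made up 902, 866 and 671 of the kept fits in the 3 comparisons. The kept totals therefore do not measure how robust the calls were. A changed sign of a gene called in neither fit was counted as kept, and there were 46 of these over the 3 comparisons. In simulated data of this depth edgeR recovered 52%, 46.5% and 46% of genes changed 2-fold in the 3 comparisons.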

Other observations

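All choices in this part were made after the results were seen. Genes called under each of 4 settings, the fit of all tumours, counts summed per title code, the fit without vehicle 2, 6 and 7, and both together, numbered 104 in relapse against vehicle (38 higher, 66 lower), 100 in stable against vehicle (53 higher, 47 lower) and 42 in both (17 higher, 25 lower). Besides Sc5d and Fdft1 they included Hif1a, the oxygen-regulated transcription factor (-0.94 ± 0.16, adjusted p = 0.00218 in relapse; -1.02 ± 0.16, adjusted p = 0.000697 in stable tumours). Higher in both were the kinase gene Rps6ka5 (0.85 ± 0.10, adjusted p = 0.000197; 1.16 ± 0.10, adjusted p = 8.55e-07) and the transcription factor gene Klf11 (1.19 ± 0.16, adjusted p = 0.000393; 1.58 ± 0.16, adjusted p = 4.84e-06). Irs2, Igf1r, Erbb3, Ccng2, Nqo1 and Mfap5 were not called under all 4 settings in either comparison. Among those called under the 4 settings in relapse against vehicle alone was the hedgehog receptor gene Ptch1 (1.41 ± 0.19, adjusted p = 0.000502); whether it differs between the BYL719 groups is a separate test, in which edgeR called 0 genes (751 at an unadjusted p under 0.05; DESeq2 called 6).

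Lists that did not pass with all tumours passed in relapse against vehicle without vehicle 2, 6 and 7: glycolysis (median -0.40, adjusted p = 0.000426), squamous epithelium (-1.37, adjusted p = 0.000243), endothelium (0.69, adjusted p = 8.08e-05), mesenchymal transition (0.56, adjusted p = 0.0122), hypoxia and angiogenesis (-0.38, adjusted p = 0.0258) and immediate early and heat shock (-0.26, adjusted p = 0.0371). With an estimated correlation in that fit these calls were lost, with adjusted p from 0.58 (glycolysis and endothelium) to 0.772 (mesenchymal transition). Squamous scores were -3.8 in vehicle 2, -3.45 in vehicle 6 and -3.91 in stable 1. Milk genes scored highest in relapse 3, at 2.6, and WNT and NOTCH targets in relapse 2, at 1.43.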
